A study of Mus musculus with 4 samples.

How the data were processed

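Polyadenylation or other selection, the read counter, the annotation release and the strand setting are not given in the sources used here. RNA was extracted from a piece of kidney kept in RNAlater and sequenced on Illumina libraries by a service company, per the labels' protocols. The submitters' processing notes name STAR 2.5.2b, DESeq2 and the mouse build GRCm38, without saying which step each served. Each sample has 1 deposited table of read counts per gene, and per the file headers these are raw counts of total, unique, exon and intron reads. Total gene reads equalled exon plus intron reads for 100% of genes. The same tables hold RPKM values that the authors computed, and for 99.7% of genes in each library these were recovered from exon reads, exon length and the library total to within a relative difference of 0.0001; RPKM was not tested. Gene and exon lengths are given in bases per the file headers. A further table holds the authors' own comparison, with a log2 fold change and its standard error, a p-value and an adjusted p-value per gene, per the file headers. That table lists 16128 genes, those with more than 40 reads over the 4 libraries, and its read counts are identical to the total gene reads of the sample tables. Its fold changes are coded saline over immune complex, since their sign opposes the read ratio for all 80 genes with an adjusted p under 0.05. All columns of samples could be matched to a sample by its title.

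Total gene reads were the counts tested. Counting reads in introns adds unspliced RNA and reads of overlapping genes, so exon reads were tried as an alternative. The depth was 19675879 to 22791960 reads per library, and reads placed at 1 location were 84.2%, 84.0%, 83.4% and 85.0% of them. Intron reads were 8.29% and 8.90% in saline and 9.96% and 7.39% in immune complex libraries. Wilson intervals of such shares cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before use: the chi-square of counts per degree of freedom was 19.7 between the saline libraries and 66.6 between the immune complex libraries, so neither pair looks like a library and its copy. Separate tissue samples exceed counting noise in any case, so this says nothing of their spread or origin. Xist reads were present in all 4 libraries and Y-linked genes had at most 10 reads, as the female label requires. The comparison was immune complex against saline with all 4 libraries (2 in each group). Replicate numbers are shared between groups in the labels, which do not say that they pair samples, so the fit had no block.

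Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment at 0.05, without a fold limit. Of 38924 genes, 16334 passed the filter. The common biological coefficient of variation was 0.212, and the fit had 2 residual and 4.61 prior degrees of freedom. Standard errors of edgeR fold changes are the fold change divided by the square root of its F statistic. CPM values use the TMM-scaled library sizes, with SD over 2 libraries. Distances, principal components and list tests used log2 CPM with a prior count of 2.

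Before the data were examined, 44 gene lists of kidney cell types, immune cells, injury, metabolism and other tissues were fixed, holding 665 list entries found in the files out of 666. Symbols were matched by gene ID, because several genes stand under older names. Lists with at least 5 tested genes, except the sex check, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over 37 lists. Lists of neutrophil, B and plasma cell, NK cell, adrenal, skeletal muscle and lymphatic endothelium markers had 4, 3, 4, 2, 4 and 4 genes with enough reads and were not tested. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit. A list can then lose its call even where its genes are not correlated. The rule for the genes named in the text was also fixed before. It took up to 12 genes per direction past the threshold with non-overlapping groups and a mean of at least 1 CPM, without gene-model numbers, small RNAs and pseudogene symbols, by fold change. Where fewer than 5 passed it filled up to 5 by the smallest unadjusted p. It added the members with the lowest p of each list (2, or 4 where the list passed, not all of them printed; some genes taken by the rule are not reported here) and Havcr1, Lcn2, C3, Fcgr4, Ccl2, Col4a1, Fn1, Nphs1, Pdgfrb, Mki67 and Adgre1. Other genes are named where a count or the closing observations needed them and were chosen after their values were seen. These were Cd14, Lgals3, S100a8, S100a9, Car3, Thrsp, Gpd1, Dgat2, Ucp1, Cidea, Cish, Socs2 and Ifi27l2a. Wnt9b, Wnt7b, Slc6a12, Slc6a6, Cldn4, Slc5a3, Krt5 and the uroplakins beyond Upk1a and Upk1b were chosen in the same way.

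The tests were checked on simulated counts for these libraries, drawn from the real means with gene-wise spread around the fitted trend, which is an assumption of the simulation. In 5 simulations with 200 changed genes, over about 16032 tested genes, edgeR recovered 0% of genes changed 2-fold and 7.6% of those changed 4-fold, with 2.2 false among 9.8 calls on average and 0 calls when nothing was changed. DESeq2 1.42.0, over 16334 genes, recovered 22.6% and 80.8%, with 77 false among 180.4 calls, and called 43.4 genes when nothing was changed. With the settings that give the deposited values (a beta prior, genes with more than 40 reads, 15942 genes), the figures were 22% and 79.6%, 74.4 false among 176 calls, and 42.8 calls. Camera called 25 of 25 lists of 20 genes shifted 2-fold and 1 of 75 unshifted lists, with genes simulated independently of each other.

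DESeq2 with a beta prior on the genes with more than 40 reads gave the authors' log2 fold changes to within 0.000281 and the same 80 genes. Alternatives covered other tests, scalings, filters, prior counts, a replicate block and leaving out each library in turn, and the closing section gives their effect. Genes with near-identical copies are uncertain in how their reads were split. Gene positions follow the files, on GRCm38: Sptssb lies on chromosome 3 from 69819538 to 69859896 (ENSMUSG00000043461, minus strand), Psca on chromosome 15 from 74714839 to 74717063 (ENSMUSG00000022598), Igfbp2 on chromosome 1 from 72824503 to 72852474 (ENSMUSG00000039323) and Cyp2e1 on chromosome 7 from 140763739 to 140774975 (ENSMUSG00000025479), each of them protein-coding in GENCODE M21, where 37607 of the 38924 gene IDs were found. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.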

Results

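RNA sequencing of a kidney piece per sample was carried out in female CB-17 SCID mice, a strain on a Balb/c background that lacks functional B and T cells. Saline or preformed immune complexes were given through the tail vein 3 times within 7 days, and tissue was taken one day after the third dose. The complexes joined IgG autoantibody with galactose-deficient IgA1, the autoantigen of IgA nephropathy, and the comparison asks what they do to the kidney transcriptome. There were 2 saline and 2 immune complex libraries. The labels name 4 kidney samples and do not state that each came from its own animal, so p-values measure the spread between these samples. Total reads assigned to genes were 19675879 and 20950134 in the saline libraries and 22791960 and 21681408 in the immune complex libraries, over 38924 listed genes.

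No gene passed the test over all 16334 genes, and the genes with the lowest p-values in each direction are described first. Sptssb, which encodes a small subunit of serine palmitoyltransferase, stood at 19.3 ± 3.84 CPM in saline and 1.54 ± 0.105 CPM in immune complex kidneys (mean ± SD, n = 2 each). Psca, an epithelial surface protein, stood at 36.6 ± 13.8 against 4.03 ± 0.379 CPM, and Igfbp2, which binds insulin-like growth factors, at 12.0 ± 1.59 against 1.07 ± 0.448 CPM. In the other direction, the cytochrome P450 Cyp2e1 stood at 140.2 ± 13.1 CPM in saline and 460.3 ± 79.1 CPM in immune complex kidneys. Tgm3, a transglutaminase, stood at 0.237 ± 0.266 against 6.38 ± 3.07 CPM, with 1 and 9 reads in the saline libraries. All 5 were among the 80 genes that the authors' deposited table calls.

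None of these values passed Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test, so they are not calls. They were taken as the 5 lowest unadjusted p-values in each direction among genes with non-overlapping groups and at least 1 CPM, without gene-model and pseudogene symbols. On the log2 scale Sptssb differed by -3.64 ± 0.28 (SE; adjusted p = 0.0876), Psca by -3.18 ± 0.32 (adjusted p = 0.221) and Igfbp2 by -3.47 ± 0.36 (adjusted p = 0.221). Cyp2e1 differed by 1.72 ± 0.21 (adjusted p = 0.381). Among other genes taken by the same rule, at an adjusted p of 0.457, Scube2 differed by -3.43 ± 0.49 and Gsdmcl2 by -1.95 ± 0.26. Rarres1 differed by 2.47 ± 0.33, Tgm3 by 4.70 ± 0.74 and Insig1, a brake on sterol synthesis, by 1.10 ± 0.17. Gsdmcl2 is a transcribed unprocessed pseudogene in GENCODE M21, since the rule left out pseudogenes by their symbol only. Every read of Gsdmcl2 lay in its introns (100%), and strand use in counting is not given in the sources used here. Reads of another transcript at that place therefore cannot be told apart from its own.

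**Figure D1:**
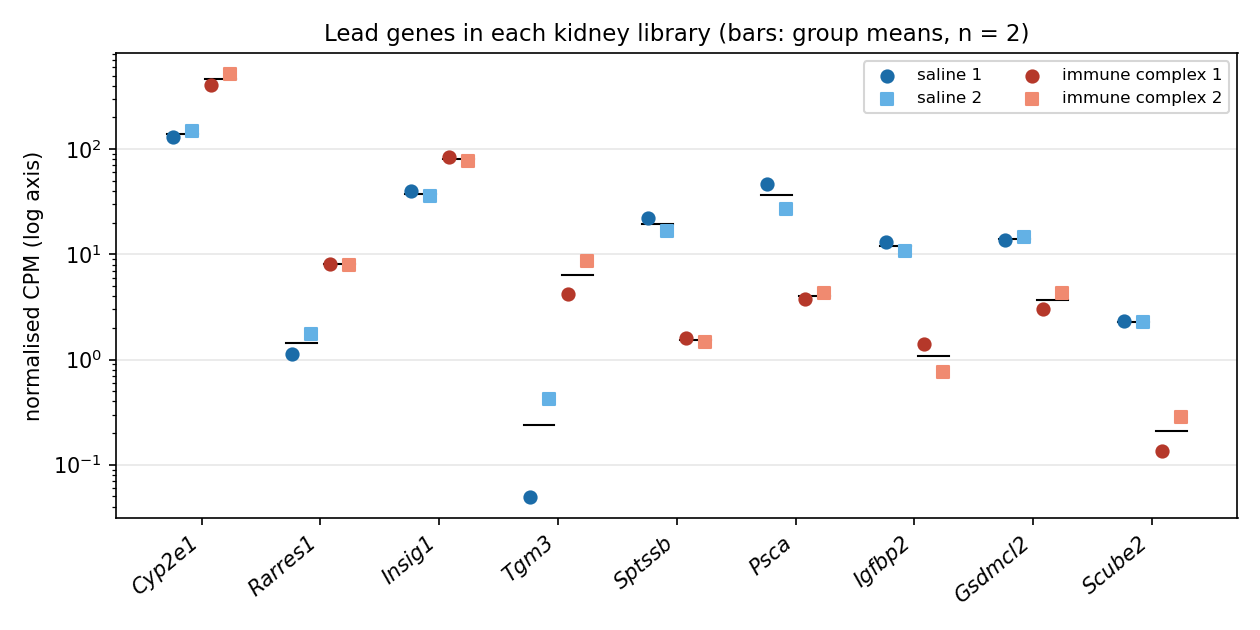
Normalised read counts (CPM, log axis) of 9 lead genes in each of the 4 kidney libraries, with group means (n = 2) as black bars. Sptssb lay at 22.0 and 16.6 CPM in saline and 1.61 and 1.46 CPM in immune complex libraries, and the groups do not overlap for any gene shown, which is part of how these genes were chosen.

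The test called 0 genes higher and 0 lower at an adjusted p of 0.05, while 749 genes had an unadjusted p under 0.05, against 817 that chance alone gives over as many tests. Of these, 324 were higher and 425 lower in immune complex kidneys. Groups did not overlap for 4899 genes (30.0%), where chance gives 33.3%. Other tools run on the same reads gave 93 genes (DESeq2, 36 higher and 57 lower) and 0 (limma-voom), and edgeR called 47 genes without saline replicate 1, 279 without saline replicate 2 and 0 without either immune complex replicate.

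Among the tested lists, those of adipocytes and of red blood cells had the highest medians. All 10 adipocyte markers had higher means in the immune complex libraries, and for 8 of them the groups did not overlap. Their median log2 fold change was 2.35 in the edgeR fit and 4.48 as a difference of mean log2 CPM. The camera adjusted p was 9.73e-07, and 0.671 with an estimated correlation. Ucp1 and Cidea stood at 20.6 and 13.9 CPM in saline 2 and at 3.64 and 2.13 CPM in immune complex 2. Adipocyte RNA also differed within the saline group. Cidec, a lipid droplet protein, stood at 0.541 and 32.2 CPM in saline 1 and 2, and at 146.6 and 155.0 CPM in the immune complex libraries. Fabp4, a fatty acid carrier, stood at 52.6, 238.2, 625.9 and 501.5 CPM, and Lep, the hormone leptin, at 0 and 1.04 CPM in saline and 6.18 and 12.8 CPM in immune complex libraries. Adjusted over the list alone, 1 adipocyte gene (Lep) was past the threshold, and over all genes 0 were. Without immune complex replicate 1 the adipocyte list did not pass (camera adjusted p = 0.0885), with a difference of mean log2 CPM of 4.002. The difference of mean log2 CPM was 1.38 without saline replicate 1 and 7.02 without saline replicate 2. Of the erythroid and platelet list, 5 of 6 tested members were higher (median log2 fold change 0.83, camera adjusted p = 1.01e-05; adjusted p = 0.664 with an estimated correlation), and all 5 were past the threshold adjusted over the list alone. Hbb-bt differed by 1.19 ± 0.21, Hbb-bs by 0.82 ± 0.20, Hba-a1 by 0.84 ± 0.19 and Hba-a2 by 0.80 ± 0.19. Alpha and beta globin copies are close to identical, so the split of reads within each pair is uncertain.

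Macrophage and humoral innate immune lists were also higher. Of 18 macrophage markers, 16 were higher in immune complex kidneys (median log2 fold change 0.41, camera adjusted p = 2.22e-05; adjusted p = 0.664 with an estimated correlation), and 3 passed when adjusted over the list alone, against 0 over all genes. Adgre1, the F4/80 antigen, listed here under its older symbol Emr1, stood at 3.47 ± 0.0961 CPM in saline and 8.48 ± 1.85 CPM in immune complex kidneys (log2 difference 1.29 ± 0.28). Lyz2, the macrophage lysozyme, differed by 0.98 ± 0.24, the protease gene Ctss by 0.94 ± 0.25 and the integrin gene Itgam by 1.30 ± 0.49 (0.84 without saline replicate 1 and 1.97 without saline replicate 2), whereas Cd14 and Lgals3 were lower. The complement list had 16 of 23 members higher (median 0.28, camera adjusted p = 0.0108; adjusted p = 0.671 with an estimated correlation). C3, the central complement component, stood at 203.7 ± 33.4 CPM in saline and 313.3 ± 3.59 CPM in immune complex kidneys (log2 difference 0.62 ± 0.19, adjusted p = 0.941), C1s differed by 0.46 ± 0.21 and Serping1, an inhibitor of C1, by -0.48 ± 0.29 (-0.03 without saline replicate 1 and -0.84 without saline replicate 2). Cfd differed by 2.57 ± 1.45 (1.58 without saline replicate 1 and 8.31 without saline replicate 2) and is also an adipocyte marker, at 1.03 CPM in saline 1 and 110.5 CPM in saline 2. Fc receptor and immune complex signalling genes were higher for 13 of 18 members (median 0.17, camera adjusted p = 0.00762; adjusted p = 0.671 with an estimated correlation). The activating receptors Fcgr3 and Fcgr4 differed by 0.78 ± 0.32 and 0.77 ± 0.35, the shared signalling chain Fcer1g by 0.62 ± 0.35 (0.25 without immune complex replicate 1) and the transferrin receptor Tfrc by 0.57 ± 0.22 (0.32 without saline replicate 2). No complement or Fc receptor gene passed over all genes or adjusted over the list alone. Without immune complex replicate 1 neither list passed, and without saline replicate 2 the Fc receptor list did not. As a difference of mean log2 CPM the complement median was 0.27, and it was 0.11 without immune complex replicate 1 and 0.15 without saline replicate 2. The Fc receptor median on that scale was 0.15, and it was 0.14 without saline replicate 2, 0.27 without immune complex replicate 1 and 0.31 without immune complex replicate 2.

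Transcripts encoded in mitochondria were higher for 12 of 13 genes (median 0.34, camera adjusted p = 0.00016; adjusted p = 0.671 with an estimated correlation), with mt-Atp8 at 0.46 ± 0.20 (0.25 without immune complex replicate 2) and mt-Nd4 at 0.38 ± 0.17. These genes took 12.6% and 14.2% of reads in the saline libraries and 15.5% and 16.1% in the immune complex libraries. The 95% Wilson interval of each share lies within 0.1 percentage points of it and covers counting error only. The 23 nuclear genes of oxidative phosphorylation had a median of -0.00 (camera adjusted p = 0.939). The mitochondrial list was not past the threshold without saline replicate 1, where its difference of mean log2 CPM was 0.22 in place of 0.34, or without saline replicate 2, where it was 0.46.

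The lists of urothelium, principal cells and the thick ascending limb were lower, whereas those of the distal convoluted and connecting tubule (4 higher and 4 lower, camera adjusted p = 0.705) and of intercalated cells (5 higher and 4 lower, camera adjusted p = 0.341) did not pass. The intercalated list had a median of 0.06, while its camera direction was lower. All 7 urothelium markers had lower means in immune complex kidneys (median log2 fold change -1.52 in the edgeR fit and -0.69 as a difference of mean log2 CPM; camera adjusted p = 0.00281; adjusted p = 0.671 with an estimated correlation). The list held 2 kinds of profile. Psca and Upk3b were high in both saline libraries, with Upk3b at 23.8 and 13.6 CPM in saline and 1.43 and 3.54 CPM in immune complex kidneys, and both passed when adjusted over the list alone. The uroplakins Upk1a and Upk1b were high in saline 2 (8.94 and 14.7 CPM) and low in saline 1 (1.48 and 1.28 CPM), and without saline replicate 2 the list's median was 0.83 and in the other direction, against -2.30 without saline replicate 1. The list did not pass without either immune complex replicate (camera adjusted p = 0.188 without replicate 1 and 0.0648 without replicate 2), where its difference of mean log2 CPM was -0.79 and -0.87. Of 10 principal cell markers 9 were lower (median -0.49, camera adjusted p = 0.00721; adjusted p = 0.732 with an estimated correlation). Aqp2, the vasopressin-regulated water channel, stood at 1704 and 544.3 CPM in saline and 528.0 and 301.9 CPM in immune complex kidneys, the transcription factor Elf5 differed by -2.01 ± 0.48 and Fxyd4, a regulator of the sodium pump, by -1.24 ± 0.29, the latter pair passing adjusted over the list alone. Without saline replicate 1 Elf5 differed by -1.19 and Fxyd4 by -0.82. As a difference of mean log2 CPM the principal cell median was -0.41, and it was -0.14 without saline replicate 1, -0.97 without saline replicate 2, -0.59 without immune complex replicate 1 and -0.13 without immune complex replicate 2. Of 10 thick ascending limb markers 9 were lower (median -0.21, camera adjusted p = 0.00281; adjusted p = 0.671 with an estimated correlation). The tight junction gene Cldn19 differed by -0.72 ± 0.20 and passed adjusted over the list alone, against 0 genes over all genes, and Bsnd, a chloride channel subunit, differed by -0.74 ± 0.24 (-0.41 without saline replicate 1). Neither tubule list passed without saline replicate 1 or without immune complex replicate 1, and the principal cell list did not pass without immune complex replicate 2. The thick ascending limb median, -0.26 as a difference of mean log2 CPM, was -0.21 without saline replicate 1, -0.16 without immune complex replicate 1 and -0.43 without immune complex replicate 2.

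Immediate early genes were lower for 14 of 16 members (median -0.31, camera adjusted p = 0.00762; adjusted p = 0.671 with an estimated correlation), with Junb at -0.61 ± 0.26 (-0.997 without immune complex replicate 1 and -0.31 without immune complex replicate 2) and Dusp1 at -0.43 ± 0.19 (-0.27 without immune complex replicate 2). Cytokines, chemokines and targets of NF-kB, the transcription factor of inflammatory signalling, were lower for 11 of 14 members (median -0.24, camera adjusted p = 0.00956; adjusted p = 0.671 with an estimated correlation), with its subunit gene Relb at -0.72 ± 0.28 and the chemokine gene Cx3cl1 at -0.45 ± 0.19. Without immune complex replicate 2 these were -0.48 and -0.28. No member of either list passed over all genes or adjusted over the list alone. Ccl2, the monocyte chemoattractant, had 5 and 0 reads in saline and 1 and 0 reads in immune complex libraries, too few to be tested. Without saline replicate 2 or without immune complex replicate 2 neither list passed, and the cytokine list also failed without saline replicate 1. As a difference of mean log2 CPM the immediate early median was -0.28, and it was -0.10 without immune complex replicate 2 and -0.16 without saline replicate 2. The cytokine median on that scale was -0.23, and it was -0.16 without saline replicate 1, -0.31 without saline replicate 2 and -0.14 without immune complex replicate 2.

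**Figure D2:**
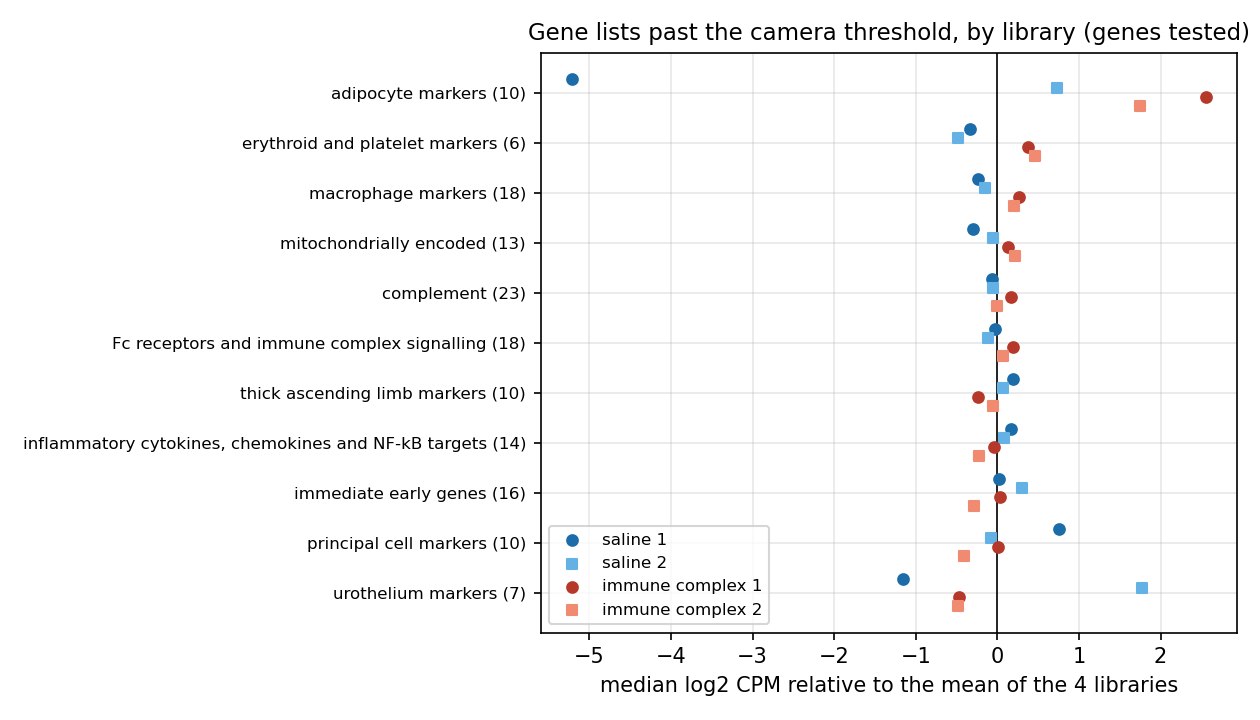
Median log2 CPM of each gene list past the camera threshold, relative to the mean of the 4 libraries, with the number of genes tested in brackets. Adipocyte markers lay at -5.21 in saline 1 and 0.73 in saline 2, against 2.55 and 1.74 in the immune complex libraries, and urothelium markers at -1.15 in saline 1 and 1.77 in saline 2.

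The remaining 26 of 37 tested lists did not pass. Tubular injury genes were mixed, with 6 higher and 11 lower (camera adjusted p = 0.210). Havcr1, the proximal tubule injury marker KIM-1, ranged from 103.8 to 186.4 CPM in saline and from 70.8 to 302.5 CPM in immune complex kidneys (log2 difference 0.36 ± 0.62), and its direction turned without immune complex replicate 2 (-1.04). Lcn2, which encodes NGAL, stood at 4.97 ± 0.274 CPM in saline and 2.70 ± 0.329 CPM in immune complex kidneys (log2 difference -0.88 ± 0.29, adjusted p = 0.957), and Krt18 differed by -1.26 ± 0.25. Extracellular matrix genes were balanced, with 12 higher and 13 lower (camera adjusted p = 0.488), and Thbs1, an activator of TGF-beta, differed by -1.34 ± 0.22. Col4a1 and Fn1, of basement membrane and interstitial matrix, differed by -0.17 ± 0.17 and -0.10 ± 0.44. The camera adjusted p was 0.488 for podocyte markers (Nphs1 0.29 ± 0.34), 0.294 for mesangial, pericyte and smooth muscle markers (Pdgfrb -0.11 ± 0.30) and 0.284 for endothelial markers (Vwf -1.61 ± 0.46, and -0.92 without saline replicate 1). It was 0.234 for proximal tubule markers, the list that holds Cyp2e1, and 0.939 for the cell cycle list (Mki67 -0.04 ± 0.48). When single libraries were left out, Fn1 ranged from -0.80 to 0.45, Nphs1 from -0.36 to 0.73, Pdgfrb from -0.61 to 0.26 and Mki67 from -0.88 to 0.49. Interferon-stimulated genes were lower for 18 of 25 members (camera adjusted p = 0.259), and T cell markers had 5 members with enough reads (camera adjusted p = 0.939). Hypoxia genes were higher for 11 of 14 members (median 0.098, camera adjusted p = 0.0564). The glycolytic enzyme gene Hk2 differed by 2.67 ± 0.62, far above that median. It stood at 0.935 and 3.78 CPM in saline 1 and 2 and at 19.9 and 10.3 CPM in the immune complex libraries. Camera gave an adjusted p of 0.552 for cholesterol synthesis genes, 0.939 for fatty acid oxidation genes and 0.720 for cytosolic ribosomal proteins. For the 19 clock genes it was 0.939, with 11 higher and 8 lower. Groups did not overlap for 6 clock genes in each direction, against 30.0% of all genes. Nr1d1 differed by -0.99 ± 0.22 and Arntl by 1.19 ± 0.46 (0.44 to 1.68 with single libraries left out). Camera asks for a shared direction, so it cannot show whether clock genes moved in opposite ways. Fry's mixed test, which takes both directions, gave the clock list an adjusted p of 0.436. Among lists too short to test, neutrophil markers were higher for 4 of 4 genes (median 0.57), adrenal markers for 2 of 2 (median 0.999) and NK cell markers for 3 of 4 (median 0.14). B and plasma cell markers were higher for 2 of 3 (median 0.57, mean -0.30), skeletal muscle markers lower for 3 of 4 (median -0.46) and lymphatic endothelium markers lower for 4 of 4 (median -0.29). With an estimated correlation 0 of the 37 lists passed, and fry, which asks whether a list's own genes move, also passed 0. For the macrophage and erythroid lists the estimated correlation was negative (-0.051 and -0.177). Their unadjusted camera p still rose from 1.80e-06 to 0.0355 and from 5.47e-07 to 0.0359. The estimated correlation therefore does not account for these lost calls. It rests on 2 residual degrees of freedom and cannot show that the genes of these lists are uncorrelated. The adipocyte list had an estimated correlation of 0.906, far above the preset 0.01. The mitochondrially encoded, principal cell and thick ascending limb lists also lay far above it, at 0.629, 0.598 and 0.406.

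The authors' deposited table listed 80 genes at an adjusted p under 0.05, where the edgeR fit had 0. Its fold changes are coded as saline over immune complex, opposite to the read ratio for all 80, and are given here with the sign turned. In the authors' deposited table so read, 30 genes were higher and 50 lower in immune complex kidneys. The authors' deposited table gives Sptssb a log2 fold change of -2.11 ± 0.21 (SE; adjusted p = 6.14e-20), Psca -1.94 ± 0.21 (adjusted p = 4.66e-17), Igfbp2 -1.71 ± 0.21 (adjusted p = 4.57e-12) and Cyp2e1 1.32 ± 0.18 (adjusted p = 3.62e-10). All 80 had the same direction and an unadjusted p under 0.05 in the edgeR fit, and for all 80 the groups did not overlap. Over the 16086 shared genes, fold changes of both sources had the same sign for 99.4% (Pearson r = 0.848, Spearman rho = 0.972 across genes, which are not independent replicates, and both come from the same reads). For 10 of the 80 genes more than 50% of reads lay in introns.

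The 2 groups did not form separate clusters. Saline 2 lay closer to immune complex 1 (Euclidean distance 58.5 over log2 CPM) than to saline 1 (64.5), and the immune complex libraries lay 74.4 apart. Saline 1 was farthest from the immune complex libraries, at 85.1 and 83.6. The mean distance between groups was 1.06 times that within groups. The first principal component held 48.1% of the variance and set saline 1 apart from both immune complex libraries, with saline 2 between them. The second held 35.8% and separated immune complex 1 from immune complex 2. Splitting 4 libraries into 2 and 2 allows no permutation p below 0.33, so no such p is given for these distances.

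**Figure D3:**
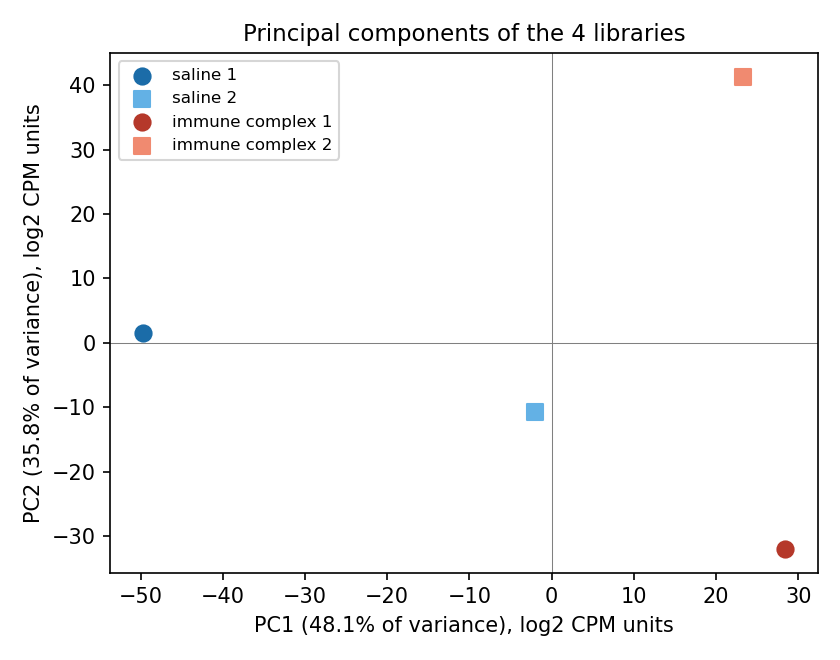
Scores of the 4 kidney libraries on the first and second principal components of log2 CPM (48.1% and 35.8% of the variance). Saline 1 lies at -49.8 and saline 2 at -1.98 on the first component, and the immune complex libraries at 28.4 and 23.3.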

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

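Tests with unique or total exon reads, without mitochondrially encoded genes, with a beta prior and with crossed pairs were chosen after the data were seen. The count of 0 genes past the threshold held for limma-voom, edgeR with robust=TRUE, RLE scaling, library totals alone, the filter of 1 CPM in 2 libraries, testing against a fold of 1.5, total exon reads and leaving out mitochondrially encoded genes. It became 93 with the DESeq2 Wald test, 80 with DESeq2 and a beta prior, and 2 without a low-count filter. It became 1 with unique exon reads and 1 at an adjusted p of 0.1. In the simulations DESeq2 called 43.4 genes when nothing was changed, and edgeR 0. DESeq2 recovered 80.8% of genes changed 4-fold there, and edgeR 7.6%. The tools thus differed in both false calls and power on simulated counts, while the cause in the real reads was not tested. Leaving out single libraries gave 0 to 279 genes (47 without saline 1, 279 without saline 2). The lone library of a group is then assumed to vary like the other group. Among 109 genes taken by the naming rule, 0 passed as reported, 23 with DESeq2, 2 without a filter, and 0 to 26 with 1 library left out. The median log2 fold change of all genes was 0.01 with TMM and -0.05 with library totals alone.

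With a replicate block the fit called 55 genes and 18 of the 109 named ones, and 11 lists. Deviations of same-numbered libraries correlated at -0.135 across genes. This rests on a single contrast per group and cannot show whether the numbers pair samples. The block was not used because the labels do not say that they do. Crossed pairs called 160 genes and 12 lists. Both fits with pairs left fewer than the 2 residual degrees of freedom of the reported fit.

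Of 37 lists, 11 passed as reported and under library totals alone, and prior counts of 0.5 and 5, and 11 of 36 with total exon reads. With an estimated correlation 0 passed, as did 0 with fry's directional and 0 with its mixed test, and 7 to 13 passed with 1 library left out. These fits tested other numbers of lists: 10 of 39 passed without saline 1, 7 of 38 without saline 2, 7 of 39 without immune complex 1 and 13 of 38 without immune complex 2, of which 7, 6, 5 and 7 were among the 11. Macrophage and erythroid lists passed without each library. In the leave-one-out fits these log2 fold changes crossed 0: Havcr1 -1.04 to 1.06, Fn1 -0.80 to 0.45, Nphs1 -0.36 to 0.73, Pdgfrb -0.61 to 0.26, Mki67 -0.88 to 0.49, Upk1a -2.30 to 0.29, Upk1b -2.43 to 1.08, Agt -0.29 to 1.38, H2-Eb1 -0.020 to 0.54, Iigp1 -1.19 to 0.22, Klhl3 -0.017 to 0.40, Rpl27 -1.14 to 0.12 and the urothelium list's median -2.30 to 0.83. The same-direction share with the authors' table was 99.4% and 99.3% over genes of at least 1 CPM, and the distance ratio 1.06 with either prior count. Rare transcripts such as Ccl2 had too few reads to be tested at this depth.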

Other observations

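The authors' deposited table calls genes beyond the fixed lists, and those named in this paragraph were chosen after their values were seen. Wnt9b and Wnt7b, ligands made by the collecting duct, had log2 fold changes of -1.14 ± 0.21 (SE) and -0.78 ± 0.21 after the sign was turned in the authors' deposited table. In the edgeR fit, whose fold changes are not shrunken, they differed by -2.18 ± 0.42 and -1.43 ± 0.43, and neither passed. Cish and Socs2, feedback inhibitors induced by growth hormone and cytokine signalling through STAT5, were both called lower in the authors' deposited table and differed by -1.10 ± 0.17 and -1.29 ± 0.29 in the edgeR fit. Ifi27l2a, an interferon-inducible gene, was called higher (1.42 ± 0.21 in the authors' deposited table), while 18 of 25 interferon-stimulated genes were lower. Over the 50 genes called lower the median log2 difference of saline 1 from saline 2 was 0.90, and 46 of them were higher in saline 1.

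The heat shock gene Hspa1b stood at 342.4 CPM in saline 1, 104.7 in saline 2 and 38.5 and 67.7 in the immune complex libraries (log2 difference -2.07 ± 0.56, adjusted p = 0.815, and -0.98 without saline 1), and it shares reads with its near-identical copy Hspa1a. Fkbp5, a glucocorticoid-induced gene, stood at 47.6 and 44.4 CPM in saline and at 76.1 and 189.3 CPM in immune complex kidneys (1.53 ± 0.40, adjusted p = 0.805, and 0.73 without immune complex 2).

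Of the tests that follow, only that of the second adipocyte list was set before its result was seen. The adipocyte genes had higher means in the immune complex libraries. A second list of 18 adipocyte genes had higher means for all 18, though not in each library. Gpd1 and Dgat2 stood at 622.3 and 267.9 CPM in saline 2 and at 471.9 and 254.0 CPM in immune complex 2. The median log2 difference of that list between saline 2 and saline 1 was 1.13. It lay just above the bound of 1 set for fat carried along with the kidney piece (median absolute deviation 1.66). Of these 18 genes, 13 reached 1 CPM in saline 1, so kidney cells or residual fat there may give part of their reads. Of those most abundant in saline 1, Gpd1 and Dgat2 differed by log2 0.20 ± 0.29 and 0.41 ± 0.25 between groups, whereas Car3 stood at 2.31 and 193.7 CPM in saline and at 679.4 and 549.9 CPM in immune complex libraries, and Thrsp at 2.36, 68.5, 213.0 and 101.1 CPM. Over the first list saline 2 exceeded saline 1 by a median log2 of 5.95, and the immune complex libraries exceeded saline 2 by 1.38. On the CPM scale saline 2 reached a median share of only 0.347 of the rise from saline 1 to the immune complex mean. Which gap is larger thus turns on the scale and on low levels in saline 1. The comparison cannot decide how much of the rise the immune complexes caused. Adipocyte RNA did differ between the saline libraries, which had no immune complexes. Perirenal fat of unequal amount is a candidate source, and an effect of the immune complexes stays open.

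For the genes lower in the authors' table, unequal pieces of the urinary tract lining and of the inner medulla were weighed. For 5 genes of the urothelium list (Upk1a, Upk1b, Upk2, Upk3a and Krt5), picked after the profiles of that list were known and without Psca and Upk3b, the median in saline 1 lay at -1.03 on the log2 scale against the immune complex mean (median absolute deviation 0.64). That choice, the single library and their low levels keep it from deciding, so a different share of urothelium stays open. The 9 inner medulla genes had a median log2 fold change of -0.54, between the bounds of -1 and -0.3. Its SE of 0.44 measures the spread between genes, not between kidneys. Of the 9 genes 7 were lower and 2 higher (Slc6a12 0.72 ± 0.41 and Slc6a6 0.55 ± 0.22). Cldn4 (-1.27 ± 0.29), a member of this list, is itself called lower in the authors' table, so the list was not independent of those calls. Slc5a3, another member, was rare, at 1.33 and 0.804 CPM in saline and 0.224 and 0.284 CPM in immune complex libraries. Relative to the 4-library mean the median of the 9 genes stood at 1.02 in saline 1, -0.10 in saline 2, -0.63 in immune complex 1 and 0.02 in immune complex 2. A different share of inner medulla in the kidney pieces could not be excluded and may contribute, and a response of the collecting duct to immune complexes stays open.

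Macrophage markers were higher in both immune complex libraries. If macrophages of fat were the source, saline 2 should exceed saline 1 by a median log2 of 0.29 over the 15 markers that were higher in immune complex libraries than in saline 1, given its adipocyte share, and it exceeded it by 0.10, with an SE of the median difference of 0.14. That SE measures the spread between genes, which are not replicates, and leaves out the spread between kidneys. The gap is too small even against that SE to decide. Blood left in the tissue would bring neutrophil RNA along with haemoglobin. S100a9 differed by 0.083 ± 0.48 and S100a8 by 1.32 ± 0.55, against 0.83 for haemoglobins. At 0.848 CPM S100a9 was too rare to decide and S100a8 was rarer still, and the 4 neutrophil markers with enough reads, all higher (median 0.57), include these 2 genes. Both stay open beside an influx or activation of macrophages.

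The 4 libraries make 3 splits into 2 and 2, too few for a share under 0.05. At an unadjusted p under 0.05 edgeR gave 749 genes for the real split and at most 841 for the others, so 2 of 3 splits gave as many. DESeq2 with the settings that give the deposited values called 80 genes for the real split and at most 29 for the others, so 1 of 3 splits gave as many.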
